A study of Homo sapiens with 15 samples.

How the data were processed

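RNA from 15 cultures of the human lung adenocarcinoma cell line A549 was measured on Affymetrix whole-transcript arrays, 1 array per culture. The cultures formed 5 groups of 3. One group was kept in normoxia with vehicle (0.1% DMSO). The other 4 groups were made hypoxic in a gas-pack pouch for 42 h after 6 h with vehicle or with 10 µM of BB2-125, BB2-162 or BB2-282, 3 compounds known by code names, which the design text calls transcriptional inhibitors. The labels call the 3 cultures of a group biological replicates. Nothing more is known of their independence, so the p-values measure the spread between these samples.

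The deposited values were intensities per probe set and array on the linear scale, for 28869 probe sets. The submitters' processing notes name RMA, which corrects background, normalises probes between arrays and summarises them per probe set. Its software, its version and the genome build were not given in the sources used here, so no coordinates are reported. The log2 was taken here before any comparison, and no value was missing or at 0. Median intensity per array ran from 74.91 to 84.6, and the number of arrays limits the precision. CA9 was not analysed here.

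The probe table listed 21062 of the probe sets, of which 19310 had 1 gene symbol and 1752 had several; another 7807 were unnamed. Symbols were checked through the Entrez ID, which was found for 19279 of the single-symbol probe sets; the symbol of the other 31 was kept as listed. For each of 18377 genes the probe set with the highest mean was used, a choice that mattered for the 685 genes with more than 1. Genes had to exceed the array's own 25th percentile of all probe sets on at least 3 arrays, which removed 2372 and left 16005 genes tested. A gene named here whose group mean lay at or below that percentile was also counted from the percentile's mean level, a bound added after seeing the data.

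Changes were tested with limma 3.58.1 in R 4.3.3, in 1 group-means fit of the 15 arrays with moderated variances (10 residual and 7.96 prior degrees of freedom). The 10 comparisons were hypoxic against normoxic vehicle, each compound against the hypoxic vehicle, each compound against the normoxic vehicle, and the 3 pairs of compounds. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. Errors given after ± are the standard errors of limma's change, with 3 arrays in each group, unless named otherwise.

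The genes named follow a rule fixed with the comparisons, gene lists and alternatives before the data were examined. For hypoxia and for each compound against the hypoxic vehicle it takes the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap. For the other comparisons it takes 3 each way. It adds up to 4 members of lowest p in each gene list described, and VEGFA, LOX, MET, CXCR4, SLC2A1, HIF1A, EPAS1, ARNT, EP300, CREBBP and CITED2 throughout the 4 comparisons with the hypoxic vehicle. The differences between compounds in those genes and in EGLN3 were chosen for display after their values were seen.

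Gene lists, 27 in number with 603 genes of which 534 were tested, came from textbook knowledge; 21 tested genes stood on more than 1 list. They covered targets of hypoxia-inducible factor (HIF), HIF pathway components, stress responses, the cell cycle, lipid synthesis, respiration, ribosomes, inflammation, detoxification, epithelial genes, markers of fibroblasts, leukocytes and endothelial cells, and housekeeping genes. The list called TGF-beta response below also holds genes of the epithelial-mesenchymal transition, among them epithelial genes such as CDH1 and EPCAM. Its direction is therefore not that of a TGF-beta response alone. Each list was tested with camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry. Camera compares a list with the other genes, whereas fry's p tests whether its members move, on balance, one way. List p-values were adjusted over the 27 lists of a comparison.

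The return of hypoxia-responsive genes towards normoxia was the slope through 0 of each compound's change on the hypoxia change. It was also counted per direction. The hypoxic vehicle arrays enter both changes, and 3 arrays cannot be split into parts of at least 2. Slopes and overlaps between compounds were therefore set beside 100 simulated draws of unchanged groups that shared the vehicle arrays. Differences between compounds over these genes were tested with fry and camera on contrasts that hold no vehicle array.

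Arrays were checked for identity and for mixed labels. No 2 arrays were identical, with 0 such pairs, and the highest correlation between arrays was 0.9961. The replicate number was checked as a pairing of cultures. In 1 of the 10 pairs of groups, hypoxic vehicle and BB2-125, each same-number correlation of deviations from the group mean was over 0.1 (0.14 to 0.27). Across the 10 pairs these correlations ran from -0.35 to 0.47. The replicate number was therefore left out of the model and used as a block in an alternative.

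The alternatives tried were quantile normalization and median centring of the arrays, no filter and a filter at the array median, the mean of a gene's probe sets, all probe sets, variance moderation with an intensity trend, array weights, fits of the 2 groups alone, a 2-fold minimum, the replicate block, other choices of hypoxia genes, and leaving out each array in turn. Added after seeing the data were a block in a fit of BB2-125 and its vehicle alone, a choice of hypoxia genes from the remaining compound, and an estimated correlation in the contrasts of compounds over the hypoxia genes. On simulated data with 200 of 16005 genes changed, the procedure recovered 59.7% to 76.1% of 1.5-fold changes, 92.5% to 100% of 2-fold changes and 100% of 4-fold changes, depending on the comparison. Among the genes called there, unchanged ones ran from 4 of 174 (BB2-282 against hypoxic vehicle) to 16 of 196 (BB2-162 against normoxic vehicle). A simulated shift of 1 gene list was called, with 0 other lists. The simulated genes varied independently, so this cannot show how often lists are called whose genes vary together.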

Results

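Gene expression was measured in 15 cultures of A549, a human lung adenocarcinoma cell line, in 5 groups of 3: normoxic vehicle, hypoxic vehicle, and hypoxia with 10 µM of one compound (BB2-125, BB2-162, BB2-282). The series asks how the compounds, given 6 h before 42 h of hypoxia, change transcription driven by hypoxia-inducible factor (HIF). No compound was given in normoxia, so an effect on that transcription cannot be told from a general effect of the compound. Median intensity per array ran from 74.91 to 84.6. The first principal component held 63% of the variance and parted the normoxic from the hypoxic arrays, and the next held 17.7%. BB2-162 replicate 1 stood apart from its group, with a root mean square deviation of 0.221 on the log2 scale against 0.094 to 0.163 for the other arrays. The lowest correlation within any group, 0.9852, was that of BB2-162 replicates 1 and 2.

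Hypoxia against normoxia asks what low oxygen did to the cells without compound. VEGFA, which encodes the angiogenic factor, rose by 3.66 ± 0.11 on the log2 scale, and the glucose transporter gene SLC2A1 rose by 2.13 ± 0.11. LOX, which encodes a collagen cross-linking enzyme, rose by 2.91 ± 0.16, and the chemokine receptor gene CXCR4 rose by 3.11 ± 0.13. HIF1A, the oxygen-regulated HIF subunit, was lower in its transcript by -2.11 ± 0.15. In total 9207 of 16005 genes were called, 4508 higher and 4699 lower, and 2732 of them changed at least 2-fold.

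The largest rises were ANGPTL4 (5.08 ± 0.16), a lipase inhibitor, CCL20 (4.90 ± 0.11), a chemokine, NDRG1 (4.15 ± 0.09), CDCP1 (4.12 ± 0.09), TNFAIP3 (4.10 ± 0.18), UGCG (4.06 ± 0.13), STC2 (3.73 ± 0.12) and ALDOC (3.70 ± 0.14). The largest falls were SLC7A11 (-5.11 ± 0.14), the cystine transporter, ESCO2 (-4.93 ± 0.14), SLC40A1 (-4.90 ± 0.11), the iron exporter, H2BC14 (-4.56 ± 0.14), IQGAP2 (-4.39 ± 0.14), HPGD (-4.36 ± 0.23), PDK4 (-4.31 ± 0.15) and OR51E1 (-4.27 ± 0.10). Each of these 16 genes had an adjusted p of 1.52e-11 or lower. CCL20 in normoxia and ESCO2 and IQGAP2 in hypoxia had mean signal at or below the dim filter, so their changes are bounds and their ranks are not measured. Counted from the filter level the bounds were 4.69, -3.48 and -4.36. Of the HIF machinery, EPAS1 rose (1.21 ± 0.12), as did CITED2 (1.87 ± 0.11), which competes with HIF for the coactivators CBP and p300, and ARNT (0.27 ± 0.11, adjusted p = 0.0368). MET rose by 0.62 ± 0.19 (adjusted p = 0.00984). The call of MET ended without hypoxic vehicle replicate 2 (adjusted p = 0.0678). That of ARNT ended after median centring (0.102), with the replicate number as a block (0.0507), and without normoxic vehicle replicate 1 (0.114), normoxic vehicle replicate 2 (0.0646), hypoxic vehicle replicate 2 (0.125) or hypoxic vehicle replicate 3 (0.0683). The coactivator genes EP300 (0.13 ± 0.19) and CREBBP (0.25 ± 0.17) did not pass.

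Of 40 tested HIF targets in signalling, survival and pH control, 33 rose, 2 fell and 5 did not pass, with NDRG1, PLIN2 (3.43 ± 0.09), ADM (3.63 ± 0.10) and VEGFA of lowest p (camera adjusted p = 3e-15, and adjusted p = 0.105 with an estimated correlation). Of 23 glycolysis and glucose uptake genes, 16 rose and 2 fell, including SLC2A3 (3.49 ± 0.10), ENO2 (2.81 ± 0.11) and HK2 (3.61 ± 0.17); the camera adjusted p was 2.72e-06, and adjusted p = 0.265 with an estimated correlation. Of 18 collagen modification and matrix genes, 10 rose and 4 fell, among them LOXL2 (3.64 ± 0.11) and P4HA2 (2.17 ± 0.11) as rises (camera adjusted p = 0.0173, adjusted p = 0.265 with an estimated correlation). In the list of HIF pathway components 6 of 14 rose and 5 fell, with a rise of EGLN3 (2.25 ± 0.12), a prolyl hydroxylase that marks HIF for degradation; the list as a whole was not called (camera adjusted p = 0.452).

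Of 31 genes of DNA replication, 29 fell and 1 rose, with GINS1 at -3.59 ± 0.10, MCM6 at -3.20 ± 0.10 and CDC6 at -4.23 ± 0.15 (camera adjusted p = 2.39e-15, adjusted p = 0.0058 with an estimated correlation). Of 32 mitosis genes, 31 fell, with KIF20A at -3.53 ± 0.11 and CDK1 at -3.16 ± 0.15 (camera adjusted p = 4.23e-16, adjusted p = 0.0962 with an estimated correlation). Replication-dependent histone genes fell in 17 of 23 cases and rose in 1, with H3C10 at -2.81 ± 0.13 (camera adjusted p = 2.53e-06, adjusted p = 0.236 with an estimated correlation). In ribosome biogenesis 21 of 28 genes fell and 5 rose, with RRS1 at -2.28 ± 0.11 (camera adjusted p = 0.000412, adjusted p = 0.236 with an estimated correlation), whereas 14 of 24 cytosolic ribosomal protein genes rose and 1 fell, with RPL7A at 0.99 ± 0.12 (camera adjusted p = 0.000751, adjusted p = 0.264 with an estimated correlation).

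Of 26 targets of NRF2, the antioxidant regulator, 24 fell and 1 rose, with TXNRD1 at -3.10 ± 0.11 and NQO1 at -2.94 ± 0.11 (camera adjusted p = 1.66e-13, adjusted p = 0.105 with an estimated correlation). Cholesterol synthesis genes fell in 14 of 18 cases, with DHCR7 at -2.36 ± 0.12 (camera adjusted p = 2.16e-06). Fatty acid synthesis genes fell in 12 of 16 cases and rose in 1, with ELOVL6 at -3.08 ± 0.11 (camera adjusted p = 8.22e-06). For both lipid lists, adjusted p = 0.105 with an estimated correlation. Heat shock genes fell in 13 of 17 cases and rose in 1, with HSP90AA1 at -2.42 ± 0.12 (camera adjusted p = 0.00014, adjusted p = 0.185 with an estimated correlation). Respiratory chain genes fell in 15 of 27 cases and rose in 2, with SDHC at -1.71 ± 0.13 (camera adjusted p = 0.0144, adjusted p = 0.448 with an estimated correlation). Interferon-stimulated genes fell in 11 of 23 cases and rose in 4, with PARP9 at -1.96 ± 0.13 (camera adjusted p = 0.0173, adjusted p = 0.265 with an estimated correlation). PARP9 lay below the dim filter in hypoxia, and its change from the filter level was -1.24.

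Of 24 NF-kB and inflammatory genes 13 rose and 4 fell, including LIF (2.70 ± 0.10), SOD2 (2.66 ± 0.10) and TNFAIP3, which restrains NF-kB (camera adjusted p = 0.000146, adjusted p = 0.105 with an estimated correlation). ATF4 targets rose in 20 of 30 cases and fell in 7, with DDIT3 at 3.31 ± 0.13 and DDIT4 at 2.66 ± 0.08 among the rises and SLC7A11 among the falls (camera adjusted p = 0.000407, adjusted p = 0.236 with an estimated correlation). Of 26 p53 targets 19 rose and 3 fell, with GADD45B at 2.37 ± 0.11 (camera adjusted p = 8.72e-05, adjusted p = 0.185 with an estimated correlation). Of 10 metallothionein and metal response genes 7 rose and 2 fell, with MT1X at 3.52 ± 0.13 (camera adjusted p = 0.0191, adjusted p = 0.236 with an estimated correlation).

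Lists not called by camera were the endoplasmic reticulum chaperones (5 of 21 rose, 8 fell, camera adjusted p = 0.344), aryl hydrocarbon receptor targets (4 of 10 rose, 5 fell, 0.344), TGF-beta response genes (12 of 24 rose, 10 fell, 0.468) and alveolar genes (3 of 18 rose, 6 fell, 0.925; mean -0.09, median 0.16). Markers of fibroblasts (0 of 5 called, 0.925), leukocytes (3 of 7 rose, 0.122) and endothelial cells (2 of 8 rose, 0.35) were not called either; the leukocyte marker of lowest p was CD68 (2.33 ± 0.08), a lysosomal protein gene. Fry called HIF pathway components (adjusted p = 0.00991), TGF-beta response genes (0.0424) and leukocyte markers (5.35e-06) as higher, and chaperones (0.029) and aryl hydrocarbon receptor targets (2.39e-07) as lower. Housekeeping genes fell in 9 of 13 cases and rose in 1 (camera adjusted p = 0.0494, adjusted p = 0.462 with an estimated correlation). That call ended after quantile normalization (0.0546) and without normoxic vehicle replicate 1 (0.0504), normoxic vehicle replicate 2 (0.0783) or hypoxic vehicle replicate 3 (0.104). Adjusted over the list alone, 449 list members were called against 439 over all genes tested, and 16 of the 27 lists kept both counts.

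**Figure D1:**
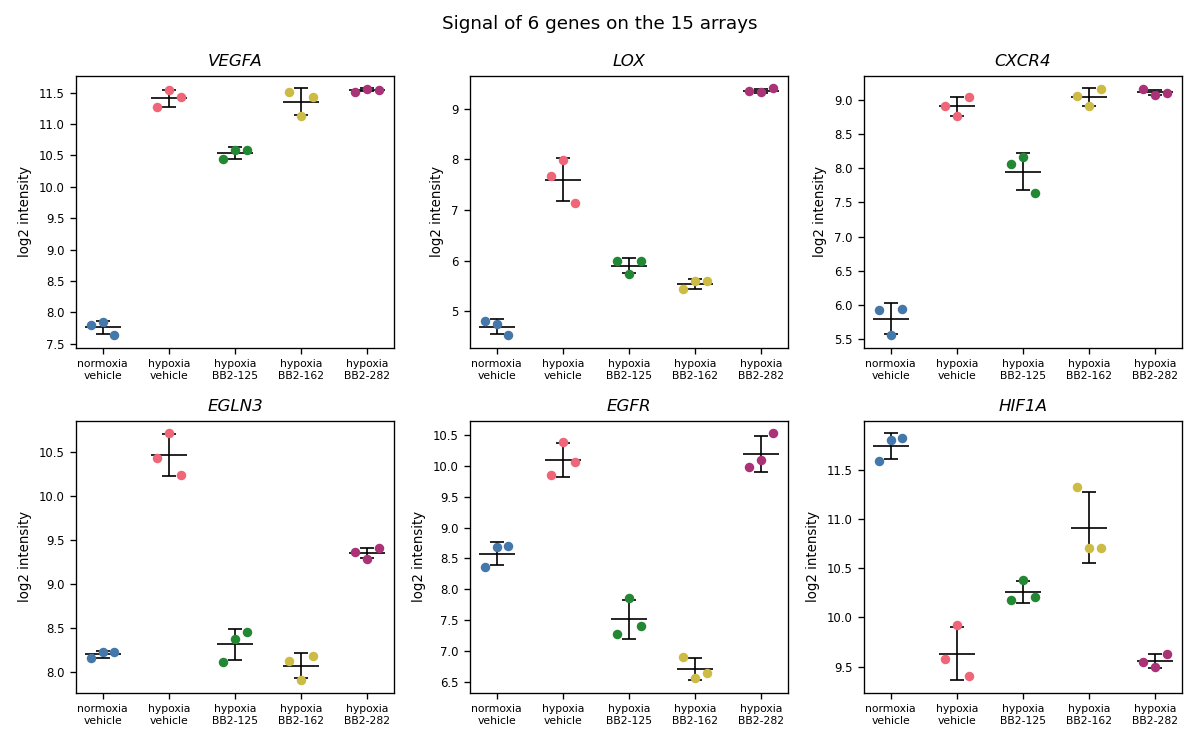
Log2 intensity (vertical axes) of VEGFA, LOX, CXCR4, EGLN3, EGFR and HIF1A in the 5 groups (horizontal axes), with 1 point per array, a dash at the mean and bars of 1 SD (n = 3). Mean LOX signal was 4.70 in normoxia, 7.60 in hypoxia, 5.90 with BB2-125, 5.54 with BB2-162 and 9.36 with BB2-282.

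BB2-125 against the hypoxic vehicle asks what this compound changed in hypoxic cells. Several HIF targets fell: VEGFA by -0.87 ± 0.11, LOX by -1.70 ± 0.16, CXCR4 by -0.95 ± 0.13, SLC2A1 by -0.52 ± 0.11 and EGLN3 by -2.15 ± 0.12. The growth factor receptor genes EGFR (-2.59 ± 0.17) and MET (-1.79 ± 0.19) fell too, to below normoxia. Their mean log2 signals were 7.51 and 8.96 with BB2-125, against 8.58 and 10.13 in normoxia. In total 4539 genes were called, 2135 higher and 2404 lower, 610 of them at least 2-fold.

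The largest rises included the small noncoding RNA genes RNU5D-1 (3.04 ± 0.59), SNORD77 (3.03 ± 0.23) and SNORD75 (2.47 ± 0.16). The other large rises were SPP1 (2.75 ± 0.11), which encodes osteopontin, NUPR1 (2.60 ± 0.12), a stress-response gene, H2BC14 (2.49 ± 0.14), EREG (2.49 ± 0.20), an EGF receptor ligand, and IDH1 (2.42 ± 0.14). The largest falls besides EGFR were TNFAIP6 (-2.60 ± 0.29), TMEM47 (-2.56 ± 0.15), TNS4 (-2.49 ± 0.14), TRAM2 (-2.46 ± 0.15), PRSS3P2 (-2.45 ± 0.16), GABRE (-2.41 ± 0.17) and PMEPA1 (-2.36 ± 0.11). The highest adjusted p among these 16 was 0.000661, for RNU5D-1. RNU5D-1 and SNORD77 in the hypoxic vehicle and TNFAIP6 with BB2-125 had mean signal below the dim filter, so their ranks are not measured; from the filter level their changes were 2.20, 2.30 and -2.51. RNU5D-1 ran from 5.32 to 8.70 over the BB2-125 arrays. HIF1A rose by 0.63 ± 0.15 (adjusted p = 0.00429), whereas EPAS1 (-1.08 ± 0.12), EP300 (-0.97 ± 0.19) and CREBBP (-1.14 ± 0.17) fell. ARNT (-0.22 ± 0.11, adjusted p = 0.146) and CITED2 (-0.28 ± 0.11, adjusted p = 0.0759) did not pass.

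Of the 40 HIF targets in signalling, 18 fell and 2 rose, with TGFA (-1.64 ± 0.11) and EDN1 (-1.59 ± 0.13) among the falls (camera adjusted p = 0.00028, adjusted p = 0.316 with an estimated correlation). Glycolysis genes fell in 9 of 23 cases and rose in 2, with GYS1 at -1.11 ± 0.14 and ALDOC at 1.21 ± 0.14 (camera adjusted p = 0.0159, adjusted p = 0.647 with an estimated correlation); that call ended without hypoxic vehicle replicate 2 (0.0733) and with fry (adjusted p = 0.0798). Matrix genes fell in 7 of 18 cases and rose in 1, with PLOD2 at -1.43 ± 0.12 (camera adjusted p = 0.00945, adjusted p = 0.293 with an estimated correlation). HIF pathway components fell in 4 of 14 cases and rose in 1 (camera adjusted p = 0.00779, adjusted p = 0.293 with an estimated correlation). TGF-beta response genes fell in 12 of 24 cases and rose in 2, with THBS1 at -1.58 ± 0.14 and SMAD7, an inhibitor of that pathway, at -1.27 ± 0.11 (camera adjusted p = 0.000829, adjusted p = 0.293 with an estimated correlation).

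Replication genes rose in 20 of 31 cases, with RFC3 at 1.50 ± 0.15 and CDC6 at 1.25 ± 0.15 (camera adjusted p = 8e-09, adjusted p = 0.0464 with an estimated correlation). Mitosis genes rose in 18 of 32 cases, with FOXM1 at 1.26 ± 0.12 (camera adjusted p = 8.58e-07), and histone genes rose in 14 of 23 cases and fell in 1, with H3C10 at 1.82 ± 0.13 (camera adjusted p = 1.02e-08); for both, adjusted p = 0.225 with an estimated correlation. Cholesterol synthesis genes rose in 14 of 18 cases, with FDPS at 1.78 ± 0.12 (camera adjusted p = 5.64e-09), and heat shock genes in 12 of 17, with HSPA6 at 1.86 ± 0.15 (camera adjusted p = 8.92e-09); for both, adjusted p = 0.0864 with an estimated correlation. ATF4 targets rose in 18 of 30 cases and fell in 4, with ASNS at 1.54 ± 0.11 (camera adjusted p = 1.86e-07, adjusted p = 0.155 with an estimated correlation). NRF2 targets rose in 15 of 26 cases and fell in 1, with NQO1 at 1.77 ± 0.11 (camera adjusted p = 1.2e-06, adjusted p = 0.274 with an estimated correlation). Fatty acid synthesis genes rose in 10 of 16 cases and fell in 1, with FADS2 at 1.35 ± 0.11 (camera adjusted p = 0.000105, adjusted p = 0.218 with an estimated correlation).

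Smaller rises came from ribosome biogenesis genes (12 of 28 rose, 1 fell, camera adjusted p = 0.000842, adjusted p = 0.293 with an estimated correlation), respiratory chain genes (10 of 27 rose, 0.00659, adjusted p = 0.418 with an estimated correlation), p53 targets (12 of 26 rose, 3 fell, 0.0208, adjusted p = 0.4 with an estimated correlation) and aryl hydrocarbon receptor targets (4 of 10 rose, 1 fell, 0.0301, adjusted p = 0.225 with an estimated correlation). The p53 call ended without hypoxic vehicle replicate 3 (0.0653). Not called by camera were chaperones (8 of 21 rose, 3 fell, 0.155), ribosomal proteins (1 of 24 rose, 1 fell, 0.197), NF-kB genes (5 of 24 rose, 5 fell, 0.818), interferon-stimulated genes (5 of 23 rose, 3 fell, 0.366), metallothioneins (1 of 10 rose, 4 fell, 0.0537) and alveolar genes (2 of 18 rose, 2 fell, 0.818). Fibroblast (0 of 5 called, 0.818), leukocyte (1 of 7 rose, 0.808) and endothelial markers (0 of 8 called, 0.335) and housekeeping genes (2 of 13 rose, 2 fell, 0.818; mean -0.01, median 0.01) were not called by camera. Metallothioneins were called as lower with no dim filter (adjusted p = 0.0346), with an intensity trend (0.0497), with fry (0.00184), and without hypoxic vehicle replicate 1 (0.0336) or BB2-125 replicate 1 (0.0194). Adjusted over the list alone, 297 list members were called against 274 over all genes tested. With the replicate number as a block 4444 genes were called, and 5352 with that block in a fit of these groups alone.

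BB2-162 against the hypoxic vehicle asks the same of the compound with the most called genes against that vehicle in the fit of all 15 arrays. EGFR fell by -3.40 ± 0.17, LOX by -2.06 ± 0.16, EGLN3 by -2.39 ± 0.12 and MET by -1.55 ± 0.19. HIF1A rose by 1.28 ± 0.15 and CITED2 by 0.73 ± 0.11. VEGFA (-0.06 ± 0.11, adjusted p = 0.704), CXCR4 (0.13 ± 0.13, adjusted p = 0.446) and SLC2A1 (-0.21 ± 0.11, adjusted p = 0.126) did not pass. In total 5780 genes were called, 2511 higher and 3269 lower, 612 of them at least 2-fold. A fit of the 2 groups alone called 3494, and median centring of the arrays moved the share of called genes that were higher from 43.4% to 28.2%.

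The largest rises were VTRNA1-1 (3.01 ± 0.47), a vault RNA gene, HSPA6 (2.93 ± 0.15) and CRYAB (2.45 ± 0.21), which encode heat shock proteins, NR4A2 (2.84 ± 0.17) and NR4A1 (2.34 ± 0.13), immediate-early nuclear receptor genes, GEM (2.71 ± 0.11), SNORD13P2 (2.59 ± 0.18) and CXCL2 (2.55 ± 0.14), a neutrophil chemokine. The largest falls besides EGFR and EGLN3 were CP (-2.56 ± 0.18), which encodes ceruloplasmin, DOCK5 (-2.44 ± 0.16), UACA (-2.30 ± 0.13), OSMR (-2.30 ± 0.16), BRD10 (-2.27 ± 0.29) and PRSS3P2 (-2.22 ± 0.16). The highest adjusted p among these 16 was 8.33e-05, for VTRNA1-1. EPAS1 (-0.50 ± 0.12), EP300 (-0.74 ± 0.19) and CREBBP (-1.09 ± 0.17) fell, and ARNT (-0.15 ± 0.11, adjusted p = 0.27) did not pass.

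Of 24 NF-kB and inflammatory genes 15 rose and 1 fell, with CXCL1 at 2.17 ± 0.13, CXCL5 at 0.86 ± 0.09 and NFKBIA, an inhibitor of NF-kB, at 1.05 ± 0.09 (camera adjusted p = 1.06e-06, adjusted p = 0.11 with an estimated correlation). Mitosis genes fell in 21 of 32 cases, with PLK1 at -1.33 ± 0.10 and TOP2A at -1.48 ± 0.17 (camera adjusted p = 1.27e-07, adjusted p = 0.583 with an estimated correlation). Heat shock genes rose in 8 of 17 cases and fell in 1, with DNAJB1 at 1.26 ± 0.12 (camera adjusted p = 0.00238, adjusted p = 0.63 with an estimated correlation). ATF4 targets rose in 13 of 30 cases and fell in 3, with PPP1R15A at 1.62 ± 0.14 (camera adjusted p = 0.00442, adjusted p = 0.63 with an estimated correlation). Matrix genes fell in 8 of 18 cases and rose in 2, with LOXL2 at -1.22 ± 0.11 (camera adjusted p = 0.012), and TGF-beta response genes fell in 12 of 24 cases and rose in 3, with THBS1 at -2.02 ± 0.14 (0.0147); for both, adjusted p = 0.63 with an estimated correlation. Glycolysis genes fell in 8 of 23 cases and rose in 1, with PFKP at -1.63 ± 0.15 (0.0454, adjusted p = 0.666 with an estimated correlation), and respiratory chain genes fell in 8 of 27 cases and rose in 2, with NDUFB5 at -1.03 ± 0.13 (0.0435, adjusted p = 0.63 with an estimated correlation).

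The HIF targets in signalling went both ways, with 10 of 40 higher and 11 lower; their mean was -0.16 and their median 0.06 (camera adjusted p = 0.65). Also not called by camera were HIF pathway components (4 of 14 rose, 5 fell, 0.711), chaperones (4 of 21 rose, 9 fell, 0.0764), replication genes (4 of 31 rose, 10 fell, 0.2), histones (5 of 23 rose, 3 fell, 0.26), p53 targets (8 of 26 rose, 6 fell, 0.362) and cholesterol synthesis (7 of 18 rose, 3 fell, 0.26). The same held for fatty acid synthesis (6 of 16 rose, 2 fell, 0.2), ribosome biogenesis (9 of 28 rose, 3 fell, 0.2), ribosomal proteins (1 of 24 rose, 2 fell, 0.632), interferon-stimulated genes (2 of 23 rose, 2 fell, 0.362), NRF2 targets (6 of 26 rose, 7 fell, 0.553), aryl hydrocarbon receptor targets (3 of 10 rose, 1 fell, 0.26) and metallothioneins (1 of 10 rose, 3 fell, 0.119). Alveolar genes (3 of 18 rose, 2 fell, 0.285), fibroblast (2 of 5 rose, 0.125), leukocyte (3 of 7 rose, 1 fell, 0.2) and endothelial markers (2 of 8 rose, 0.071) and housekeeping genes (5 of 13 fell, 0.0515) were not called by camera. Fry called as lower chaperones (adjusted p = 0.0182), replication genes (0.00464), metallothioneins (0.00464) and housekeeping genes (0.0204). As higher it called cholesterol (0.0465) and fatty acid synthesis (0.0418), aryl hydrocarbon receptor targets (0.0221) and fibroblast (0.0147), leukocyte (0.0244) and endothelial markers (0.0159). Camera called housekeeping genes with no dim filter (0.0238), an intensity trend (0.0476) or the replicate block (0.0483), and without hypoxic vehicle replicate 3 (0.0278) or BB2-162 replicate 1 (0.0148). It called endothelial markers without hypoxic vehicle replicate 1 (0.0457) or BB2-162 replicate 1 (0.029), and chaperones with no dim filter (0.0384) or without BB2-162 replicate 1 (0.029). Adjusted over the list alone, 285 list members were called against 261 over all genes tested.

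Projected over all tested genes on the change of replicates 2 and 3, the change of BB2-162 replicate 1 from the hypoxic vehicle was 60.5%. No spread of this share was measured, and not every gene responded less. LOX (log2 signal 5.436, against 5.600 and 5.594 in replicates 2 and 3) and HIF1A (11.329, against 10.708 and 10.704) lay further from the vehicle. EGFR (6.902, against 6.565 and 6.635) and VTRNA1-1 (7.397, against 9.707 and 8.619) lay nearer. The fit without replicate 1 called 7698 genes, and the calls of ATF4 targets and of the respiratory chain ended (0.0505 for both). The glycolysis call ended after quantile normalization (0.14) and without hypoxic vehicle replicate 2 (0.126), BB2-162 replicate 2 (0.151) or BB2-162 replicate 3 (0.0977). The respiratory chain call also ended after quantile normalization (0.203) and without hypoxic vehicle replicate 1 (0.148) or BB2-162 replicate 3 (0.0977), and the TGF-beta call ended after quantile normalization (0.0569).

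BB2-282 against the hypoxic vehicle asks the same of the compound with the fewest called genes. LOX rose further by 1.76 ± 0.16, and FGB (-3.10 ± 0.17) and MUC5B (-1.68 ± 0.20) fell. EGLN3 fell by -1.11 ± 0.12. VEGFA (0.13 ± 0.11), CXCR4 (0.20 ± 0.13), SLC2A1 (-0.05 ± 0.11), MET (-0.34 ± 0.19), HIF1A (-0.08 ± 0.15), EPAS1 (-0.09 ± 0.12), ARNT (0.10 ± 0.11), EP300 (0.33 ± 0.19), CREBBP (0.27 ± 0.17) and CITED2 (-0.15 ± 0.11) did not pass. In total 2176 genes were called, 905 higher and 1271 lower, 157 of them at least 2-fold.

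The 8 largest rises by log2 change were of noncoding RNA genes: RNU5D-1 (5.31 ± 0.59), a spliceosomal RNA, VTRNA1-1 (4.92 ± 0.47), SNORA46 (4.02 ± 0.29), SNORA65 (3.93 ± 0.33), SCARNA4 (3.82 ± 0.19), SNORA75 (3.70 ± 0.25), SNORA41 (3.25 ± 0.23) and SNORA80E (3.01 ± 0.33). SNORA genes encode RNAs that guide pseudouridylation. The largest falls besides FGB, a fibrinogen chain, and MUC5B, a mucin, were CST1 (-2.25 ± 0.16), a cystatin, TM4SF20 (-2.03 ± 0.22), CP (-1.89 ± 0.18), SPX (-1.77 ± 0.17), H4C8 (-1.71 ± 0.19) and AGR2 (-1.62 ± 0.14). The highest adjusted p among these 16 was 2.95e-05, for MUC5B. RNU5D-1 lay below the dim filter in the hypoxic vehicle, so its rank is not measured and its rise is a bound, 4.47 from the filter level.

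**Figure D2:**
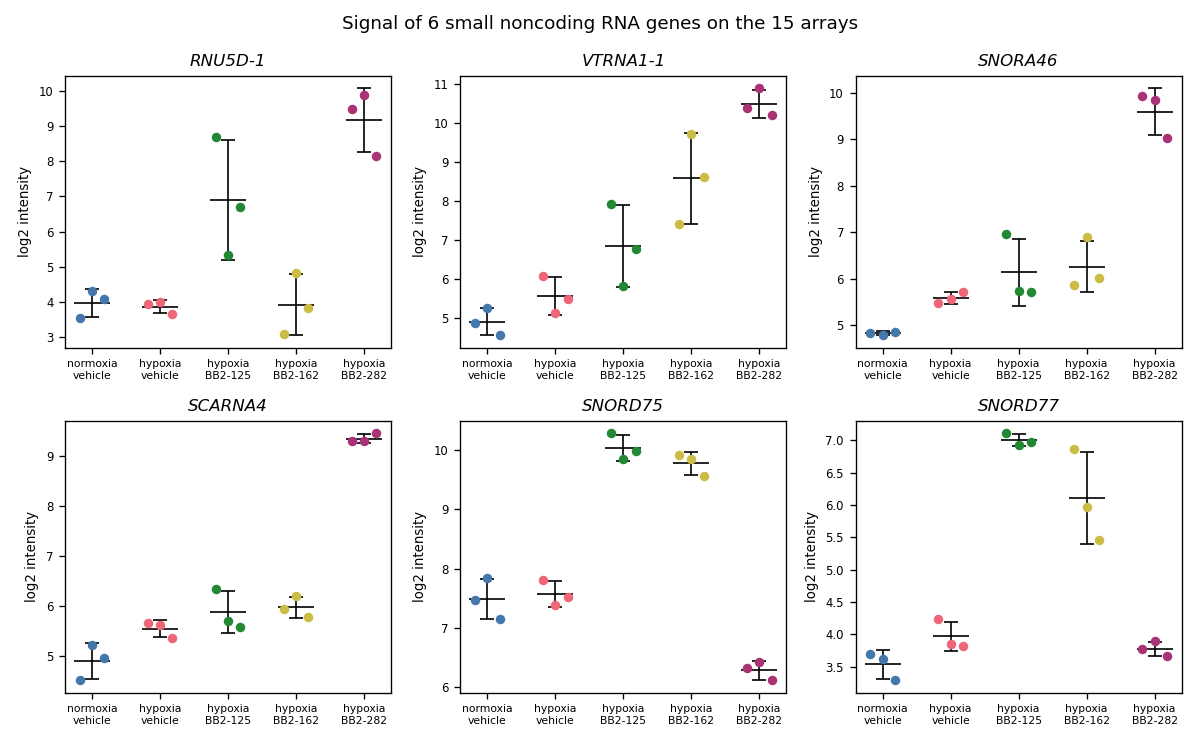
Log2 intensity (vertical axes) of 6 small noncoding RNA genes in the 5 groups (horizontal axes), with 1 point per array, a dash at the mean and bars of 1 SD (n = 3). Mean SCARNA4 signal was 5.54 in hypoxia and 9.36 with BB2-282, and mean SNORD75 signal was 7.57 in hypoxia, 10.04 with BB2-125 and 6.28 with BB2-282.

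Matrix genes rose in 9 of 18 cases and fell in 1, with COL4A2 at 0.94 ± 0.11 and ITGA5 at 0.95 ± 0.17 (camera adjusted p = 2.64e-05, adjusted p = 0.219 with an estimated correlation). TGF-beta response genes rose in 8 of 24 cases, with TAGLN at 1.29 ± 0.10 and THBS1 at 0.84 ± 0.14 (camera adjusted p = 0.000232, adjusted p = 0.325 with an estimated correlation). NF-kB and inflammatory genes rose in 10 of 24 cases and fell in 2, with ICAM1 at 1.79 ± 0.10 and CCL20 at -1.17 ± 0.11 (camera adjusted p = 0.000138, adjusted p = 0.219 with an estimated correlation). Cholesterol synthesis genes rose in 9 of 18 cases and fell in 1, with STARD4 at 0.97 ± 0.12 (camera adjusted p = 2.74e-06, adjusted p = 0.219 with an estimated correlation), and fatty acid synthesis genes rose in 6 of 16, with FADS2 at 0.89 ± 0.11 (0.000151, adjusted p = 0.277 with an estimated correlation). Respiratory chain genes fell in 10 of 27 cases, with COX5B at -1.20 ± 0.15 (camera adjusted p = 2.74e-06), ribosomal protein genes in 8 of 24, with RPS15 at -0.69 ± 0.14 (3.72e-05), and heat shock genes in 7 of 17, with DNAJA1 at -0.67 ± 0.09 (0.00035); for these 3 lists, adjusted p = 0.277 with an estimated correlation. Histone genes fell in 6 of 23 cases and rose in 1, with H2BC4 at -0.77 ± 0.12 (camera adjusted p = 0.000138), and ribosome biogenesis genes fell in 5 of 28 cases, with WDR74 at -0.81 ± 0.15 (0.00493); for both, adjusted p = 0.44 with an estimated correlation. Mitosis genes rose in 7 of 32 cases, with CENPF at 0.73 ± 0.14 (camera adjusted p = 0.00539, adjusted p = 0.506 with an estimated correlation), and p53 targets rose in 4 of 26, with FAS at 0.83 ± 0.11 (0.0208, adjusted p = 0.495 with an estimated correlation).

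HIF targets in signalling (4 of 40 rose, 4 fell, camera adjusted p = 0.798), glycolysis genes (1 of 23 rose, 2 fell, 0.59) and HIF pathway components (1 of 14 fell, 0.744) were not called by camera. Nor were ATF4 targets (6 of 30 rose, 3 fell, 0.278), chaperones (2 of 21 fell, 0.0529), replication genes (2 of 31 rose, 4 fell, 0.744; mean -0.04, median 0.01), interferon-stimulated genes (1 of 23 fell, 0.352), NRF2 targets (3 of 26 rose, 5 fell, 0.642), aryl hydrocarbon receptor targets (2 of 10 rose, 0.0786) and metallothioneins (2 of 10 rose, 0.162). The same held for alveolar genes (2 of 18 fell, 0.809; mean -0.04, median 0.06), fibroblast (1 of 5 rose, 0.278), leukocyte (0 of 7 called, 0.441) and endothelial markers (0 of 8 called, 0.435) and housekeeping genes (1 of 13 rose, 2 fell, 0.203). Fry called aryl hydrocarbon receptor targets (adjusted p = 0.0201) and metallothioneins (0.0208) as higher. Camera called ATF4 targets (0.0473) and aryl hydrocarbon receptor targets (0.0422) after quantile normalization, and the latter (0.0471) and metallothioneins (0.0492) without hypoxic vehicle replicate 2. It called chaperones with no dim filter (0.039) and without hypoxic vehicle replicate 1 (0.0189), BB2-282 replicate 2 (0.0415) or BB2-282 replicate 3 (0.025). Adjusted over the list alone, 174 list members were called against 142 over all genes tested. The count of called genes rested on single arrays: 1222 were called without hypoxic vehicle replicate 1, 1352 without hypoxic vehicle replicate 2 and 1258 without BB2-282 replicate 2, and array weights gave 4193. The mitosis call ended without hypoxic vehicle replicate 3 (0.403), as did that of p53 targets (0.163), which also ended without BB2-282 replicate 3 (0.0536). With fry neither mitosis genes (adjusted p = 0.119) nor p53 targets (0.0671) passed.

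**Figure D3:**
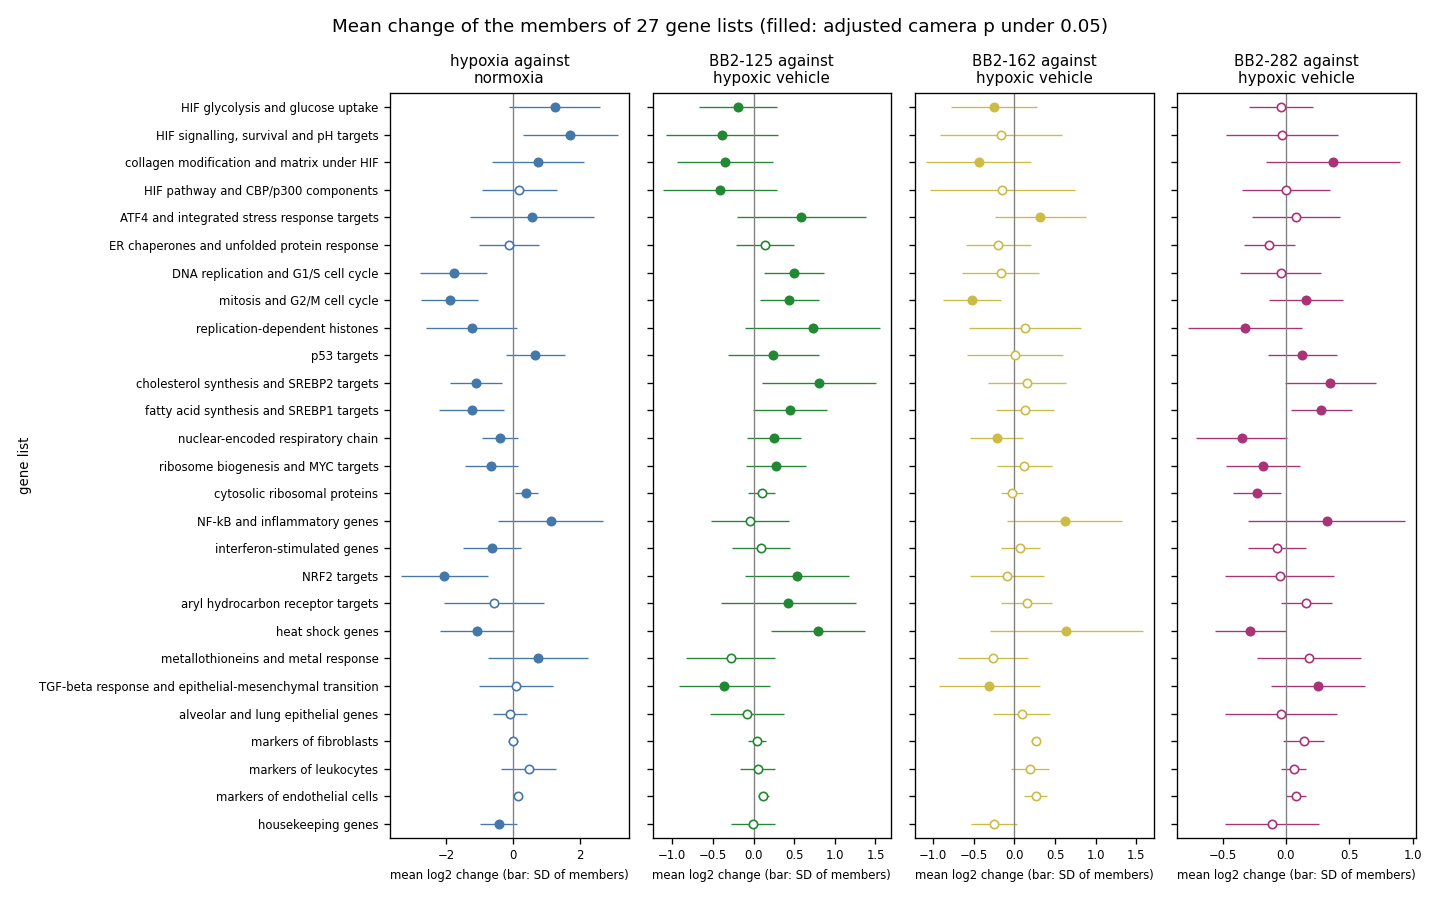
Mean log2 change (horizontal axes, a separate scale per panel) of the members of 27 gene lists (vertical axis) in hypoxia against normoxia and with each compound against the hypoxic vehicle. Bars are 1 SD over list members, and filled points have an adjusted camera p under 0.05; DNA replication genes stood at -1.78 in hypoxia and at 0.50 with BB2-125.

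The compounds were compared directly at the same dose and time. VEGFA was lower with BB2-125 than with BB2-162 (-0.82 ± 0.11) or BB2-282 (-1.01 ± 0.11), as was CXCR4 (-1.09 ± 0.13 and -1.16 ± 0.13). LOX was lower with BB2-125 (-3.46 ± 0.16) and BB2-162 (-3.82 ± 0.16) than with BB2-282, and so was MET (-1.45 ± 0.19 and -1.21 ± 0.19). HIF1A was higher with BB2-162 than with BB2-125 or BB2-282 (BB2-125 minus BB2-162 -0.66 ± 0.15, BB2-162 minus BB2-282 1.36 ± 0.15). Between BB2-125 and BB2-162 no difference passed for LOX (0.36, 95% interval 0.03 to 0.68, adjusted p = 0.0965), MET (-0.25, -0.65 to 0.16), EP300 (-0.23, -0.62 to 0.16), CREBBP (-0.05, -0.40 to 0.30) or EGLN3 (0.25, -0.01 to 0.50). Between BB2-162 and BB2-282 none passed for VEGFA (-0.19, -0.42 to 0.04), CXCR4 (-0.07, -0.35 to 0.21), SLC2A1 (-0.17, -0.39 to 0.06) or ARNT (-0.25, -0.47 to -0.02, adjusted p = 0.0788).

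Genes of the HIF machinery also differed between compounds. EP300 (-1.30 ± 0.19 and -1.07 ± 0.19), CREBBP (-1.41 ± 0.17 and -1.36 ± 0.17) and EGLN3 (-1.04 ± 0.12 and -1.28 ± 0.12) were lower with BB2-125 and with BB2-162 than with BB2-282. CITED2 was lower with BB2-125 than with BB2-162 (-1.01 ± 0.11) and higher with BB2-162 than with BB2-282 (0.87 ± 0.11), and between BB2-125 and BB2-282 no difference passed (-0.13, 95% interval -0.37 to 0.10). EPAS1 was lower with BB2-125 than with BB2-162 (-0.58 ± 0.12) or BB2-282 (-0.99 ± 0.12). Between BB2-162 and BB2-282 EPAS1 differed by -0.41 ± 0.12 (adjusted p = 0.0129), a call that ended without BB2-162 replicate 2 (0.0882) or BB2-282 replicate 3 (0.0549). HIF1A was higher with BB2-125 than with BB2-282 (0.70 ± 0.15). ARNT was lower with BB2-125 than with BB2-282 (-0.32 ± 0.11, adjusted p = 0.0256), and that call ended without BB2-125 replicate 1 (0.0728) or 3 (0.0578), or BB2-282 replicate 2 (0.0821) or 3 (0.0739). For ARNT between BB2-125 and BB2-162 no difference passed (-0.07, -0.29 to 0.16). SLC2A1 was lower with BB2-125 than with BB2-282 (-0.47 ± 0.11) and than with BB2-162 (-0.30 ± 0.11, adjusted p = 0.0457). The latter call ended after median centring (0.125), in a fit of these groups alone (0.152), with the replicate number as a block (0.0613), without any 1 of the BB2-125 arrays (0.177, 0.0503 and 0.0794 for replicates 1 to 3), and without BB2-162 replicate 1 (0.153) or 3 (0.0622).

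BB2-125 against BB2-162 gave 4182 called genes, 2672 higher with BB2-125 and 1510 lower, and 305 at least 2-fold. RNU5D-1 (2.99 ± 0.59), UPK1B (2.10 ± 0.16) and C5 (2.07 ± 0.18), a complement gene, were higher with BB2-125, and CEACAM5 (-2.32 ± 0.15), CST1 (-2.15 ± 0.16) and NR4A2 (-2.08 ± 0.17) were lower. RNU5D-1 lay below the dim filter with BB2-162, and its difference from the filter level was 2.06. Mitosis genes were higher with BB2-125 in 30 of 32 cases, with CCNB2 at 1.64 ± 0.13 (camera adjusted p = 2.1e-22, adjusted p = 0.0233 with an estimated correlation), and replication genes in 21 of 31, with RRM2 at 1.98 ± 0.15 (camera adjusted p = 1.41e-12, adjusted p = 0.0103 with an estimated correlation). NF-kB genes were lower with BB2-125 in 17 of 24 cases, with CXCL8 at -1.81 ± 0.15 (camera adjusted p = 3.34e-11, adjusted p = 0.0103 with an estimated correlation). Without BB2-162 replicate 3 the count of called genes was 2645, in a fit of the 2 groups alone it was 2582, and median centring moved the share that was higher from 63.9% to 74.4%.

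BB2-125 against BB2-282 gave 5813 called genes, 2992 higher and 2821 lower, and 1039 at least 2-fold. SNORD75 (3.76 ± 0.16), FGB (3.58 ± 0.17) and SNORD77 (3.22 ± 0.23) were higher with BB2-125, and VTRNA1-1 (-3.65 ± 0.47), SCARNA4 (-3.50 ± 0.19) and LOX were lower. SNORD77 lay below the dim filter with BB2-282, and its difference from the filter level was 2.28. Heat shock genes were higher with BB2-125 in 15 of 17 cases, with HSPH1 at 2.29 ± 0.14 (camera adjusted p = 3.3e-10, adjusted p = 0.0787 with an estimated correlation). Matrix genes were lower in 12 of 18 cases and higher in 1, with COL5A1 at -1.26 ± 0.12 (camera adjusted p = 1.94e-05, adjusted p = 0.189 with an estimated correlation).

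BB2-162 against BB2-282 gave 5734 called genes, 2489 higher and 3245 lower, and 767 at least 2-fold. NR4A2 (3.51 ± 0.17), SNORD75 (3.50 ± 0.16) and CST1 (3.15 ± 0.16) were higher with BB2-162, and RNU5D-1 (-5.26 ± 0.59), LOX and SNORA65 (-3.81 ± 0.33) were lower. RNU5D-1 lay below the dim filter with BB2-162, and its difference from the filter level was -4.33. Mitosis genes were lower with BB2-162 in 26 of 32 cases and higher in 1, with TOP2A at -1.81 ± 0.17 (camera adjusted p = 6.39e-11), and matrix genes in 11 of 18, with LOXL2 at -1.67 ± 0.11 (camera adjusted p = 1.02e-06); for both, adjusted p = 0.178 with an estimated correlation. Median centring moved the share that was higher from 43.4% to 32.9%.

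Each compound was also set against the normoxic vehicle, as the design text does. BB2-125 gave 9916 called genes (5041 higher, 4875 lower, 2694 at least 2-fold), with rises of ALDOC (4.91 ± 0.14), DDIT3 (4.52 ± 0.13) and CCL20 (4.36 ± 0.11) and falls of SLC40A1 (-4.84 ± 0.11), OR51E1 (-4.76 ± 0.10) and IQGAP2 (-4.54 ± 0.14). BB2-162 gave 12296 (6785 higher, 5511 lower, 3437 at least 2-fold), with rises of CCL20 (5.77 ± 0.11), TNFAIP3 (5.56 ± 0.18) and PPP1R15A (4.95 ± 0.14) and falls of HPGD (-5.32 ± 0.23), SLC40A1 (-4.98 ± 0.11) and TM4SF20 (-4.88 ± 0.22). Its median change over all genes was 0.139, and 0.028 after median centring of the arrays. BB2-282 gave 10372 (5346 higher, 5026 lower, 3211 at least 2-fold), with rises of VTRNA1-1 (5.58 ± 0.47), RNU5D-1 (5.21 ± 0.59) and SNORA46 (4.77 ± 0.29) and falls of TM4SF20 (-6.17 ± 0.22), FGB (-5.70 ± 0.17) and PDK4 (-5.24 ± 0.15). Median centring turned the share of called genes that were higher from 50.8% to 44.6% with BB2-125, from 55.2% to 47.3% with BB2-162 and from 51.5% to 46.5% with BB2-282, and quantile normalization gave 49.3%, 52.5% and 51%. In normoxia CCL20 and RNU5D-1 lay below the dim filter, as did IQGAP2 with BB2-125 and SLC40A1 with BB2-162, so their changes are bounds. From the filter level CCL20 changed by 4.15 with BB2-125 and 5.56 with BB2-162, RNU5D-1 by 4.57, IQGAP2 by -4.30 and SLC40A1 by -4.94. Replication genes stayed below normoxia in 26 of 31 cases with BB2-125, 29 with BB2-162 and 30 with BB2-282 (adjusted p = 0.025, 0.00914 and 0.00874 with an estimated correlation). NF-kB genes were above normoxia in 15 of 24 cases with BB2-125, 21 with BB2-162 and 20 with BB2-282 (adjusted p = 0.166, 0.0336 and 0.0768 with an estimated correlation).

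The return towards normoxia was measured by slope and by count. Over the 9207 hypoxia genes the change with BB2-125 was 16% of the hypoxia change in the opposite direction (arrays 15.7% to 16.5%), against a mean slope of 0.01976 (-0.036 to 0.092) in simulated unchanged groups that share the vehicle arrays. By count 59.7% of these genes moved back, within the simulated range of 39.3% to 75.3% (mean 57.55%). Of the 4508 genes higher in hypoxia 1125 fell and 334 rose with BB2-125, and of the 4699 lower genes 1239 rose and 618 fell. With BB2-162 1027 of the higher genes fell and 707 rose, and 565 of the lower genes rose and 1323 fell. More genes thus fell than rose in both sets with BB2-162, which a single slope does not show. With BB2-282 358 of the higher genes fell and 415 rose, and 233 of the lower genes rose and 587 fell. The slope was -1.2% for BB2-162 (arrays -5.4% to 4.3%) and -4.7% for BB2-282 (arrays -5.7% to -3.4%). Over the HIF lists it was 12.5% for BB2-125, 6.3% for BB2-162, which turns the sign, and -0.8% for BB2-282, and without hypoxic vehicle replicate 2 that of BB2-282 was -2.5%. The simulated slopes ran from -0.047 to 0.082 for BB2-162, whose -0.012 lay inside, and from -0.037 to 0.091 for BB2-282, whose -0.047 lay below. By count 42.4% and 44.2% moved back, within the simulated 35.6% to 76.5% and 37.5% to 73.3%. In direct contrasts, genes higher in hypoxia were lower with BB2-125 than with BB2-162 (mean -0.094, fry p = 0.000162, and p = 0.0104 in camera with an estimated correlation) or BB2-282 (-0.163, fry p = 3.98e-06, and p = 0.0102). Genes lower in hypoxia were higher with BB2-125 than with BB2-162 (0.235, fry p = 0.000789, and p = 0.0205) and BB2-282 (0.184, fry p = 0.00424, and p = 0.16 with an estimated correlation). Over the HIF lists these 2 calls ended: the lower genes gave 0.048 and 0.072, neither past fry's threshold, while the higher genes kept theirs (-0.151 and -0.338). The lower genes there were the minority of list members with a negative hypoxia change, called or not. Being far fewer, they say little about the 4699 lower genes. Genes chosen from the remaining compound, after seeing the data, gave -0.033 in higher and 0.056 in lower genes for BB2-125 against BB2-282, neither past that threshold, and kept both calls against BB2-162 (-0.118 and 0.248). Between BB2-162 and BB2-282 the means were -0.069 (fry p = 0.00524, and p = 0.381 with an estimated correlation) and -0.051 (fry p = 0.32), and genes chosen from the remaining compound reversed the former to 0.098. Without BB2-162 replicate 1 the former was -0.043 and no longer passed fry's threshold, while the latter was -0.118 and passed it.

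The changes of the compounds against the hypoxic vehicle correlated across genes at 0.643 for BB2-125 and BB2-162, 0.044 for BB2-125 and BB2-282 and 0.226 for BB2-162 and BB2-282; genes are not independent replicates. Without hypoxic vehicle replicate 3 the last 2 were 0.149 and 0.36. Simulated unchanged groups sharing the vehicle arrays gave mean correlations of 0.4631, 0.543 and 0.5007 and highest ones of 0.875, 0.942 and 0.914, so none of the 3 lay above the simulated range. Those groups hold no compound effect, so shared vehicle noise makes up more of their correlation than of the real one. The comparison of correlations therefore cannot decide whether responses were shared. The covariance was 0.1172 for BB2-125 and BB2-162 against a simulated mean of 0.009623, a difference of 0.1076, and above the simulated highest of 0.03603. For the other pairs the covariance was 0.005613 and 0.02946, below the simulated highest of 0.03678 and 0.04328. BB2-125 and BB2-162 shared 853 risen and 1681 fallen genes, where independent calls would share 335 and 491, and 169 genes went opposite ways, where independence gives 813.2. BB2-125 and BB2-282 shared 192 and 303 (120.7 and 190.9 if independent), with 550 opposite (305.5). BB2-162 and BB2-282 shared 199 and 528 (142 and 259.6), with 333 opposite (384.3). The counts for independent calls take no account of the shared vehicle arrays.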

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

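The tests of differences between compounds were planned, and no explanation was tested for the values in this part. Several gene lists were called in opposite directions with a pair of compounds, often through a minority of their members. LOX went down with BB2-125 and BB2-162 and up with BB2-282, a difference of -3.46 between BB2-125 and BB2-282 and of -3.82 between BB2-162 and BB2-282. The collagen modification and matrix list differed by a mean of -0.72 and -0.81 in the same pairs, and TGF-beta response genes by -0.61 and -0.56. Against the hypoxic vehicle 7 of 18 matrix genes fell and 1 rose with BB2-125, 8 fell and 2 rose with BB2-162, and 9 rose and 1 fell with BB2-282. Of 24 TGF-beta genes 12 fell and 2 rose, 12 fell and 3 rose, and 8 rose and 0 fell with limma, in the same order. Against the hypoxic vehicle these list calls were lost with an estimated correlation (BB2-125, BB2-162, BB2-282: adjusted p = 0.293, 0.63 and 0.219 for matrix genes, 0.293, 0.63 and 0.325 for TGF-beta). The TGF-beta call of BB2-162 also ended after quantile normalization (0.0569). Of 17 heat shock genes 12 rose with BB2-125, 8 rose and 1 fell with BB2-162, and 7 fell with BB2-282. The list means differed by 1.07 and 0.92 from BB2-282, and the calls against the vehicle were lost too (adjusted p = 0.0864, 0.63 and 0.277 with an estimated correlation). Of the list differences from BB2-282, 17 were called for BB2-125 and 9 for BB2-162, and 0 of either with an estimated correlation.

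Of 32 mitosis genes 18 rose with BB2-125, 7 rose with BB2-282 and 21 fell with BB2-162, with mean differences of 0.97 for BB2-125 against BB2-162 and -0.68 for BB2-162 against BB2-282. The calls against the hypoxic vehicle were lost with an estimated correlation (adjusted p = 0.225, 0.583 and 0.506 for BB2-125, BB2-162 and BB2-282). The call of BB2-282 ended without hypoxic vehicle replicate 3 (0.403) and with fry (adjusted p = 0.119). With an estimated correlation the difference of BB2-125 from BB2-162 stayed called (adjusted p = 0.0233). Of 27 respiratory chain genes 10 rose with BB2-125, 8 fell and 2 rose with BB2-162, and 10 fell with BB2-282; the list mean with BB2-125 differed by 0.47 from BB2-162 and by 0.6 from BB2-282. With an estimated correlation these calls were lost (adjusted p = 0.418, 0.63 and 0.277 in the same order, and 0.142 for the difference from BB2-162), and that of BB2-162 ended after quantile normalization (0.203). Of 23 replication-dependent histones 14 rose and 1 fell with BB2-125, and 6 fell and 1 rose with BB2-282 (difference of means 1.05). Of 28 ribosome biogenesis genes 12 rose and 1 fell with BB2-125, and 5 fell with BB2-282 (0.46). These calls were lost with an estimated correlation (adjusted p = 0.225 and 0.44 for histones, 0.293 and 0.44 for ribosome biogenesis). Some of the list calls behind these contrasts rested on single arrays, as given with each comparison above.

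Probe sets with no name here or with several gene symbols entered no comparison above and also carried signal. Of 5691 such probe sets past the dim filter, 2724 were called in hypoxia against normoxia, of which 2104 were higher and 620 lower. With BB2-125 against the hypoxic vehicle 858 were called (509 higher, 349 lower), with BB2-162 1601 (1165 higher, 436 lower) and with BB2-282 533 (228 higher, 305 lower).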

How the results depend on the processing

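Alternatives chosen after seeing the data were hypoxia genes taken from the remaining compound, the estimated correlation in the contrasts of compounds, and the replicate block in a fit of BB2-125 and its vehicle alone; where no cause is named, the cause was not tested. A 2-fold minimum, which removes small changes by construction, left 2732, 610, 612 and 157 genes (hypoxia, then BB2-125, BB2-162 and BB2-282 against the hypoxic vehicle), 2694, 3437 and 3211 against normoxia, and 305, 1039 and 767 between compounds. Fits of 2 groups alone gave 3494 for BB2-162 against the hypoxic vehicle and 2582 for BB2-125 against BB2-162. Such fits hold fewer arrays in every comparison, so array number alone does not set these apart. The fit of all arrays gives the 5 groups 1 spread, though BB2-162 arrays deviated by 0.158 to 0.221 from their group mean and the others by 0.094 to 0.149. Array weights gave 4193 for BB2-282 against the hypoxic vehicle. The replicate block gave 4444 genes for BB2-125 (5352 with its vehicle alone) against 4539. Without 1 array, counts ran from 1222 to 2393 for BB2-282 against the hypoxic vehicle and from 2645 to 6208 for BB2-125 against BB2-162. The other alternatives left these gene counts within 1.5 times. With an estimated correlation the lists called fell to 1, 1, 0 and 0, to 1, 2 and 1 against normoxia, and to 3, 0 and 0 between compounds. Quantile normalization gave 5 lists and fry 18 for BB2-162 against the hypoxic vehicle, and fry 22 for BB2-125 against normoxia. The return with BB2-125 (16%) was 16.7% over genes changed 2-fold, 12.5% over the HIF lists and 14.5% to 17.5% without 1 array. It was 14% over genes chosen without the hypoxic vehicle arrays, from the other compounds against the normoxic vehicle. The normoxic arrays thus entered both that choice and the hypoxia change. Over the HIF lists it was 6.3% for BB2-162 and -0.8% for BB2-282, which ran from -5.3% to -2.5% without 1 array. In genes lower in hypoxia the HIF lists gave differences of 0.048 (fry p = 0.603) for BB2-125 against BB2-162 and 0.072 (fry p = 0.547) against BB2-282; an estimated correlation left 0.184 at p = 0.16. Genes from the remaining compound, which hold that compound's own response, gave -0.033 in higher and 0.056 in lower genes for BB2-125 against BB2-282, neither past the threshold of fry. For BB2-162 against BB2-282 they gave 0.098 (fry p = 0.0048), a reversed sign, in higher genes and -0.2 (fry p = 0.00485) in lower genes; the estimated correlation left -0.069 at p = 0.381. Without 1 array these differences ran from -0.124 to -0.043 and from -0.118 to -0.011; without BB2-162 replicate 1 the -0.043 no longer passed fry's threshold and the -0.118 now did. Correlations of BB2-282 with BB2-125 ran from -0.01 to 0.149 and with BB2-162 from 0.152 to 0.36, the higher values without hypoxic vehicle replicate 3. Of 259 gene results, 230 of them called, 0 changed sign and 5 lost a call under any alternative; in all, 21 of 3108 recomputed values lost a call and 8 gained one. Most of these genes were named for large changes or low p in the same data, so their stability says little about the other called genes.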

Other observations

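The tests of small noncoding RNAs in hypoxia and of BB2-162 replicate 1 as an array of a BB2-125 culture were chosen only after the results were seen. Many small noncoding RNA genes rose in hypoxia; the class was not tested as a set. Of 174 tested snoRNA, scaRNA, snRNA, vault, RNase P and RNase MRP genes 131 were called higher and 0 lower with limma, with a median change of 0.98. C/D snoRNAs, which guide methylation, rose in 77 of 82 cases (median 1.13), H/ACA snoRNAs, which guide pseudouridylation, in 32 of 54 (0.68) and scaRNAs in 13 of 16 (1.37). SnRNAs rose in 6 of 15 cases (0.36), vault RNAs in 1 of 3 (0.66), RNase P and MRP RNAs in 1 of 2 (0.64) and other snoRNAs in 1 of 2 (0.45). MicroRNA precursors rose in 44 of 88 cases (0.29), and protein-coding genes had a median of 0.07.

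Against the hypoxic vehicle 38 of the 174 rose and 6 fell with BB2-282, 35 rose and 0 fell with BB2-162, and 24 rose and 13 fell with BB2-125. MicroRNA precursors rose in 32 of 88 cases and fell in 1 with BB2-162. With BB2-282 the pattern was uneven. H/ACA snoRNAs rose in 19 of 54 cases (median 0.47) and snRNAs in 7 of 15 (0.52), while C/D snoRNAs rose in 7 of 82 and fell in 3 (-0.13). Scaling of whole BB2-282 arrays was argued against by their median log2 signals (6.292 to 6.335), which lay close to those of the hypoxic vehicle (6.271 to 6.326). After quantile normalization 102.7% of the median change of the 38 risen genes stayed. On arrays this alike that step could change little, so it adds no separate evidence. More small RNA carried through extraction would raise the classes together. In the group means they did not rise alike: C/D snoRNAs were higher in 39% of cases, scaRNAs in 56.2%, H/ACA snoRNAs in 77.8% and snRNAs in 100%. The spread of each class between arrays was not measured. Of all the 174 genes 57.5% were higher (37.9% to 74.1% over pairs of arrays), a spread that leaves such a carry-over open. In hypoxia 94.8% were higher (89.7% to 97.1%), so more small RNA carried through extraction in the hypoxic samples may account for that rise, and an effect of low oxygen on these RNAs remains untested.

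The change ran lower in longer than in shorter genes in hypoxia without compound, and further with BB2-125 and BB2-162, by rises of short genes as well as falls of long ones. Across 14875 protein-coding genes the Spearman correlation of the change with genomic length was -0.145 for hypoxia (arrays -0.185 to -0.085), with 4 of 5 classes of mean signal at -0.1 or lower, and -0.121 for BB2-282 against normoxia. In hypoxia 34.7% of the longest genes fell and 24.9% rose (median 0), against 18.6% and 34.2% of the shortest (median 0.19). Against the hypoxic vehicle the correlation was -0.203 for BB2-125 (arrays -0.221 to -0.17), -0.281 for BB2-162 (-0.324 to -0.12) and 0.031 for BB2-282 (-0.079 to 0.142); genes are not independent replicates. Of the longest genes (87.9 kb or more) 26.8% fell with BB2-125 against 6.3% of the shortest (8 kb or less), and 31.2% against 8.6% with BB2-162, but 6.5% against 9.3% with BB2-282. Of the shortest 15.4% rose with BB2-125 (median 0.07) and 23.7% with BB2-162 (0.18), and of the longest 8.7% with either (-0.06 and -0.1). Dim signal of long genes was argued against, since 4 and 5 of the 5 classes of mean signal kept a correlation of -0.1 or lower for BB2-125 and BB2-162 (0 for BB2-282). Of contrasts that hold no vehicle array, BB2-162 against BB2-282 gave -0.283 (5 of 5 classes at -0.1 or lower), and BB2-125 against BB2-282 gave -0.181 (3 of 5), nearer 0 than the -0.2 named beforehand for the changes against the vehicle. Transcript length, RNA integrity and any mechanism were not tested.

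BB2-162 replicate 1 lay apart from replicates 2 and 3. A weaker response in that culture is an account left open. Its difference from one of the others followed the reversed compound response of the remaining one at r of 0.418 and 0.493. Any sample that holds less of the BB2-162 response would tend to give a positive r. The test therefore does not favour a weaker response over a mixed sample or one from outside. Scale of the array was argued against, as 97.9% of its deviation stayed after quantile normalization. The ratio of its distance to the nearest other group, BB2-125, to that to its own was 1.078 (0.358 and 0.332), but its nearest BB2-125 array lay at 0.326 against 0.348 for the nearest of its own, so this distance alone did not part them. Arrays of the other 3 groups lay at 0.41 or more, against at most 0.354 for its own. Over 6208 genes parting the 2 compounds without it, replicate 1 stood at 59.1% of the way to BB2-162. BB2-125 arrays ran from -7.2% to 4.8%. BB2-162 replicates 2 and 3, each on the axis of the other, lay between 80.9% and 108.5%. Replicate 1 was thus outside the range of both groups. Its place above the BB2-125 arrays argues against a BB2-125 culture and, with the distances, against a wrong label among the groups of this series. A mixed sample and a sample from outside were not tested.

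Splits of the 6 arrays of each comparison into 3 and 3 number 10, the real one included, too few for a share under 0.05. Only the real split, 1 of 10, reached the real count of genes in each of the 10 comparisons. In the other splits the real difference enters the spread within groups, which lowers their gene counts by construction. Their gene counts therefore do not show how many calls would come without a difference. Nor do their list counts, since these splits still hold part of the real difference between the groups. The highest other split called 0 genes, except 1120 for BB2-162 against the hypoxic vehicle (real 5780) and 71 for BB2-125 against BB2-162 (real 4182). The other real counts were 9207 for hypoxia, 4539 and 2176 for BB2-125 and BB2-282 against the hypoxic vehicle, 9916, 12296 and 10372 against normoxia, and 5813 and 5734 for BB2-125 and BB2-162 against BB2-282. For gene lists, the number of splits calling as many, the real count and the highest other were 1, 19 and 16 for hypoxia, 1, 17 and 15 for BB2-125, 6, 8 and 11 for BB2-162 and 1, 12 and 10 for BB2-282. Against normoxia they were 6, 11 and 16, then 3, 16 and 17, then 2, 18 and 18 in the same order of compounds. Between compounds they were 3, 16 and 17 for BB2-125 against BB2-162, 1, 17 and 15 for BB2-125 against BB2-282 and 6, 9 and 13 for BB2-162 against BB2-282. For BB2-125 and its vehicle, where same-numbered arrays deviated together, 4 splits part all 3 pairs, of which 1 called as many genes, and the highest other was 0.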
